A study of Mus musculus with 20 samples.

How the data were processed

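RNA of the hippocampus of wild-type mice was extracted with Trizol, made into stranded mRNA libraries and sequenced on an Illumina NextSeq. The labels give 4 groups, Young, Old, Cohoused Young and Cohoused Old, with 5 samples each. The table used here holds 19 of the 20 libraries, since Old 5 has no column and was not analysed here. Every column was assigned by the group and number in its name. The labels do not state the sex, age, cage or cage mates of a mouse. All columns, of Young and Old and of mice cohoused or not, carry the mark cohousing_3mo. It cannot be the age of both the Young and the Old mice, and what it stands for is not stated.

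The deposited values are a normalized signal on a linear scale: columns sum to 965918 to 1042101, as CPM values divided by a scaling factor per library would. The submitters' notes name kallisto 0.46.0, R 4.1.2 and GRCm38 without their order, and the authors' scaling method and gene filter are not stated there. More low values of a library than chance gives lay on exact multiples of a step, which was read as the value of 1 read and lay between 0.1068 and 0.4465. The excess was 174 to 430 values per library, and at most 12.0 where the values had been moved at random by about 1%. Dividing each total by its step gave an estimated depth of 2.243 to 9.259 M reads per library. A count of 3 reads, taken as the limit that a value of 0 allows, is a value of 0.32 to 1.34. These limits cover counting error only. Of the low values, 31.8 to 33.9% were whole multiples within 0.1, where 20.0% would be by chance. Most values were thus not whole, so that the depths are estimates and no count-based test was applied.

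The table has 16340 named genes and a single entry without a name, which held 0.0418 to 0.1162% of the total and was left out. Genes with a value of at least 1 in at least 5 libraries were tested, which kept 15532 genes and removed 808. Values were analysed as log2(value + 1) with limma-trend (limma 3.58.1, R 4.3.3) in a model with 1 mean per group and all 19 libraries. The 6 contrasts were Old vs Young, Cohoused Young vs Young, Cohoused Old vs Old, Cohoused Old vs Cohoused Young, the age difference averaged over both housings, and the interaction of age and cohousing. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Gene positions are those of GENCODE M21 on GRCm38. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

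A set of 41 gene lists covered neuronal activity, ageing, immune cells, glia, neurons, synapses, vessels, neighbouring tissue, hormone and stress responses, and metabolism. Each list was tested in each contrast with camera at a preset correlation of 0.01, adjusted over the 41 lists, and again with an estimated correlation. Their members were also counted with an adjusted p over the list alone. Genes are named by a rule. It takes, among genes past the threshold with a mean of at least 1, the 8 highest and the 8 lowest changes and the 4 in each direction with the lowest p, or, where fewer than 10 genes passed, all of them and the 10 lowest p. For each list described it takes up to 4 members with the lowest p, and in every contrast C4b, Gfap, Fos, Arc, Egr1, Npas4, Bdnf and Ttr. The groups, contrasts, tests, filter, lists, naming rule and the alternatives other than those named at the end were fixed before the data were examined.

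The method was tested on simulated data with changes of 1.5, 2 and 4-fold in 3 simulations of 598 changed genes in all. In Old vs Young it found 55.0% of them with 16 false calls, and in the age average 70.9%. The immediate early genes were also lowered 1.5-fold in Cohoused Young. Apart from these genes, 0 false calls were made in Cohoused Young vs Young and in the interaction. In Cohoused Old vs Old, which held no simulated change, 0 were made. In Cohoused Young vs Young camera found the lowered list in all 3 simulations and called 0 of 120 tests of other lists. The simulated genes were drawn independently of each other, so these false calls do not cover correlated genes or libraries that stand apart. In regroupings of the real libraries, described at the end, up to 22 lists and 86 genes were called in this contrast. The alternatives tried were other scalings, filters and pseudocounts, limma without its trend, only the libraries of the groups compared, replicate number as a block, library number or the level of choroid plexus markers as a term, and leaving out each library in turn. Limma-voom on estimated reads, weights per library, fits without libraries that stood apart, quantile scaling of the list tests and an exact permutation of list scores were added after seeing the data.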

Results

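Gene expression was measured by RNA sequencing in the hippocampus of 19 mice: 5 Young, 4 Old, 5 Cohoused Young and 5 Cohoused Old. The estimated depth was 3.488 to 6.469 M reads in Young, 2.845 to 4.273 in Old, 2.243 to 4.499 in Cohoused Young and 2.345 to 9.259 in Cohoused Old. Between 14538 and 14896 genes had a value of at least 1 in a library. The first principal component held 14.7% of the variance and set Cohoused Young 2 apart, at -69.8. That library also had the highest Gfap, an astrocyte filament, at 2979, and the highest Ttr, a choroid plexus transport protein, at 7931. Values below are the normalized values of the table as mean ± SD per group. Changes are log2 fold changes with their standard error (SE) and limma adjusted p.

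The comparison of Old with Young asked how the hippocampus differed with age in mice that were not cohoused. Klk6, Plin4, Apod and Ide were among the genes higher in Old. Klk6, a serine protease of oligodendrocytes (ENSMUSG00000050063, chromosome 7, 43824499 to 43832030), rose from 1.25 ± 0.622 (n = 5) in Young to 11.9 ± 5.89 (n = 4) in Old, a log2 change of 2.44 (SE 0.44, adjusted p = 0.0242). Plin4, a coat protein of lipid droplets (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803), rose from 15.3 ± 8.91 to 77.2 ± 16.2, a log2 change of 2.38 (SE 0.31, adjusted p = 0.00143). Apod, a lipid-binding secreted protein (ENSMUSG00000022548, chromosome 16, 31296192 to 31314808), rose from 138 ± 20.9 to 334 ± 95.9, by 1.23 (SE 0.24, adjusted p = 0.0386). Ide, the insulin-degrading enzyme (ENSMUSG00000056999, chromosome 19, 37268743 to 37337852), rose from 22.8 ± 3.42 to 47.1 ± 4.06, by 1.02 (SE 0.14, adjusted p = 0.00221).

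Transcription factors induced by neuronal activity were lower in Old. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) fell from 35.8 ± 18.6 in Young to 6.89 ± 0.406 in Old, a log2 change of -2.04 (SE 0.41, adjusted p = 0.0473). Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718) fell from 88.7 ± 22.5 to 37.6 ± 10.4, a log2 change of -1.21 (SE 0.21, adjusted p = 0.0161). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) fell from 160 ± 38.6 to 75.2 ± 12.2, a log2 change of -1.06 (SE 0.21, adjusted p = 0.0473). Sox11, a transcription factor of immature neurons, fell by 1.04, and Tmem181a fell by 1.01, from 308 ± 20.4 to 153 ± 20.4 (adjusted p = 0.0105). In all, 22 genes passed, 14 higher and 8 lower. The others named by the rule were Mid1 (1.93), Kirrel2 (1.65), Cln6 (1.02), Entpd4 (1.01) and Entpd4b (0.87), which were higher, and Olfr648 (-1.52), Tmem181b-ps (-1.43) and Tmem100 (-0.94), which were lower. Tmem181a and Tmem181b-ps, and Entpd4 and Entpd4b, are pairs of near-identical copies, between which the assignment of reads is uncertain. The labels do not give the source of the mice. A difference in colony or substrain between the age groups was not tested for these copies or for any other gene. It cannot be told apart from age by these labels. In the age average described below, with each library left out in turn, 9 to 52 called genes had another called gene within 1 Mb. They were 9 of 20 without Old 4 and 52 of 158 without Cohoused Young 1. How many scattered genes would have such a neighbour was not computed. C4b, a complement protein, had a log2 change of 1.70 and an adjusted p of 0.0765, and the values of Arc (-1.02), Npas4 (-0.85), Bdnf (-0.34), Gfap (-0.34) and Ttr (0.73) had adjusted p from 0.340 to 0.944.

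**Figure D1:**
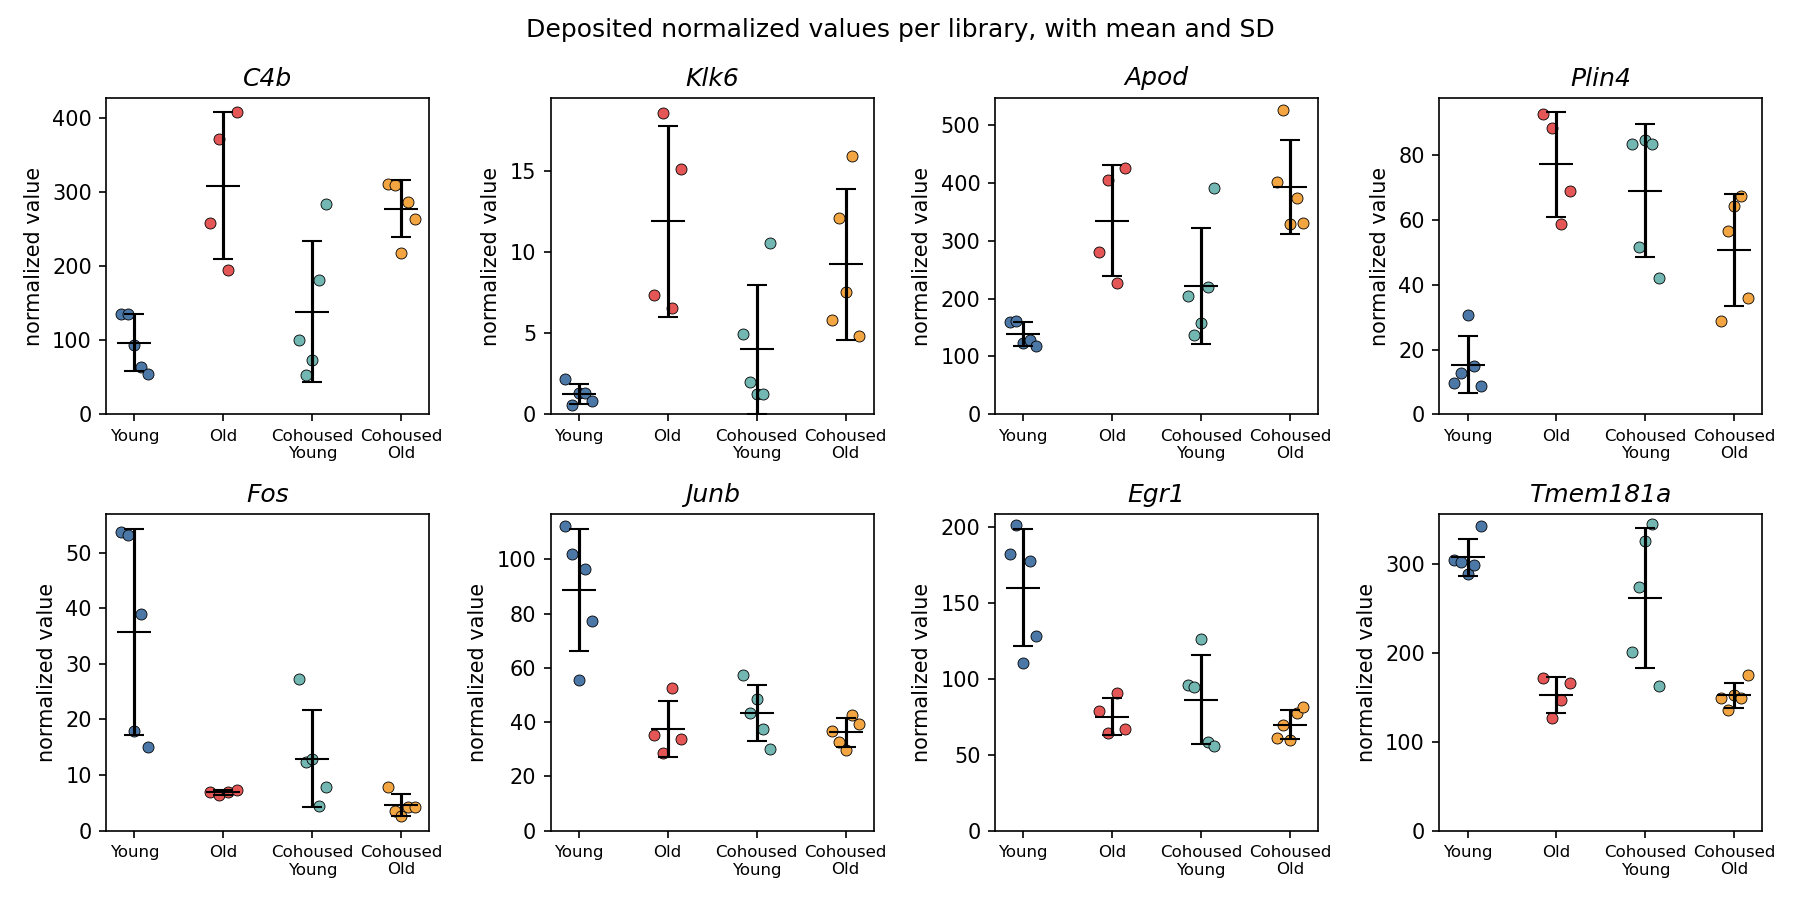
Each panel plots the normalized value of a gene on a linear axis from 0, with a point per library and the mean and SD of the 4 groups. The Fos values of the 4 Old libraries had an SD of 0.406 and those of the 5 Young libraries an SD of 18.6.

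Of 23 measured immediate early genes, which neuronal activity induces within a short time, 22 were lower and 1 was higher in Old than in Young, with a median log2 change of -0.91. Fos, Junb and Egr1 were the 3 called over all genes, and 17 were lower when adjusted over the list alone, Nr4a1 (-1.11) among them. With each of 9 libraries left out in turn, Fos lost its call in 7 fits, Junb in 5 and Egr1 in 8. All 3 lost it without Young 4 and without Young 5. The list had adjusted p = 3.62e-19 by camera and adjusted p = 0.0130 with an estimated correlation. Of 22 delayed activity-regulated genes, 19 were lower, 0 were called over all genes and 8 were lower adjusted over the list alone, with Inhba at -1.33 and Rgs4 at -0.66. Of 23 heat shock and protein folding genes, 22 were lower, 0 were called and 7 were lower adjusted over the list alone, with Dnajb5 at -0.71 and Calr, an endoplasmic reticulum chaperone, at -0.52. Both lists had adjusted p = 0.0130 with an estimated correlation. By exact permutation of list scores, an alternative added after seeing the data, the immediate early and heat shock lists did not pass, while the delayed activity list did. Young 4 and 5 had the highest Lif of the Young libraries, at 35.7 and 29.4, and the highest Fos, at 53.7 and 53.2. Without this pair of libraries, an alternative chosen after seeing the data, the median of the immediate early genes was -0.72.

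Of 22 measured myelin and mature oligodendrocyte genes, 21 were higher in Old, 2 were called, Klk6 and Apod, and 11 were higher adjusted over the list alone, including Hapln2 (0.96) and Mobp (0.73). Their median was 0.51, and the call was lost with an estimated correlation (adjusted p = 0.155 with an estimated correlation). Of 34 genes known to rise with age in mouse brain, 32 were higher, 1 was called and 8 were higher adjusted over the list alone, with adjusted p = 0.202 with an estimated correlation. Of 26 microglia activation genes, 23 were higher, 0 were called and 5 were higher adjusted over the list alone, with Lyz2 at 1.84 (adjusted p = 0.202 with an estimated correlation). Of 17 complement genes, 14 were higher and 1, C4b, passed adjusted over the list alone (adjusted p = 0.300 with an estimated correlation). In all, camera called 16 of the 41 lists at the preset correlation, 11 higher and 5 lower, and 3 held with an estimated correlation. Library totals without further scaling gave 17 higher and 6 lower genes. The count was 4 without Young 4 and 5, 7 without Old 2, 8 without Old 4 or Young 5, 9 without Old 1, 10 without Young 4 and 13 without Young 3. It was 9 with library number as a term, and 67 with a weight per library and 59 in limma-voom with quality weights, both chosen after seeing the data.

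The comparison of Cohoused Young with Young asked whether the hippocampus of young mice differed with cohousing. Plin4 rose from 15.3 ± 8.91 (n = 5) in Young to 69.1 ± 20.6 (n = 5) in Cohoused Young, a log2 change of 2.18 (SE 0.29, adjusted p = 0.00424). Fads1, a desaturase of fatty acid synthesis (ENSMUSG00000010663, chromosome 19, 10182888 to 10196877), rose from 191 ± 34.1 to 317 ± 28.8, by 0.74 (SE 0.13, adjusted p = 0.0226). Egr4 and Homer1 fell: Egr4, an activity-induced transcription factor (ENSMUSG00000071341, chromosome 6, 85511121 to 85513589), from 19.3 ± 4.16 to 7.82 ± 1.14, a log2 change of -1.19 (SE 0.19, adjusted p = 0.0226), and Homer1, a postsynaptic scaffold protein (ENSMUSG00000007617, chromosome 13, 93299635 to 93405129), from 123 ± 20.3 to 76 ± 12, a log2 change of -0.69 (SE 0.13, adjusted p = 0.0426). In all 10 genes passed, 6 higher and 4 lower, but 0 passed with only the libraries of the groups compared, with library number as a term or in limma-voom with quality weights. Library number ran from 31 to 42 in Cohoused Young and from 36 to 50 in Young, so that it cannot be fully told apart from cohousing here. Fbn1, encoding fibrillin-1 (1.02), Prodh, proline dehydrogenase (1.00), and Sgk3 (0.95) were higher, and Stx8 (-0.80) was lower. The ribosomal protein pseudogene Rps13-ps2 was also lower, at 13.5 ± 7.86 in Young and 0.963 ± 1.52 in Cohoused Young. No log2 change is given for it or for any gene below whose mean in a compared group lay under the mean value of 3 reads of that group, since such a change depends on the pseudocount. Fos (-1.44, adjusted p = 0.157), Junb (-1.01, adjusted p = 0.0610) and Egr1 (-0.92, adjusted p = 0.117) did not pass, nor did C4b, Gfap, Arc, Npas4, Bdnf or Ttr.

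Of 23 immediate early genes, 22 were lower in Cohoused Young than in Young, with a median of -0.58; 1 was called, Egr4, and 13 were lower and 1 higher adjusted over the list alone (adjusted p = 0.0874 with an estimated correlation). Of 22 delayed activity-regulated genes, 20 were lower, 1 was called, Homer1, and 7 were lower adjusted over the list alone, with Sik1 at -1.01 and Inhba at -1.05. Of 23 heat shock and protein folding genes, 22 were lower, 0 were called and 7 were lower adjusted over the list alone, with Manf at -0.71 and Pdia6 at -0.44. Both of these lists had adjusted p = 0.0413 with an estimated correlation, and 0.170 without Cohoused Young 1. Of 20 glucocorticoid-responsive genes, 14 were higher and 1 was called, Plin4; adjusted over the list alone 5 were higher and 3 lower, with Hif3a at 1.54 and Zbtb16 at 0.88 (adjusted p = 0.319 with an estimated correlation). Of 53 ribosomal protein genes 50 were lower, with a median of -0.22, and 2 passed adjusted over the list alone, Rpl35 and Rpl24 (adjusted p = 0.866 with an estimated correlation). The count of genes was 0 without Young 4 and 5, 1 without Young 4, 2 without Young 5, 3 without Cohoused Young 3, 5 without Young 3, 18 without Young 1, 25 without Cohoused Young 2 and 32 without Cohoused Young 1. Of 100 regroupings of the libraries, 5 gave as many genes, the labelled groups included.

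The comparison of Cohoused Old with Old asked whether the hippocampus of old mice differed with cohousing. By limma 0 genes passed, 493 genes had an unadjusted p under 0.05 where 777 would be expected by chance, and limma-voom with or without quality weights, weights per library and limma without its trend also gave 0. The lowest p belonged to Fanci, a DNA repair gene, at 0.255 ± 0.364 (n = 4) in Old and 3.95 ± 1.75 (n = 5) in Cohoused Old (adjusted p = 0.542). The next were Mapkapk3 (1.42), Ppp4r3b (-0.60), Rnf4 (-0.63), Tpm3-rs7 (2.32 ± 0.899 and 0.578 ± 0.677), Agps (-0.69), Tnpo2 (-0.46), She (0.93), Entpd1 (1.22) and Utp6 (0.69), none of which passed. Klk6, Apod, C4b and Clec7a, which were higher with age, had similar means in these groups: Apod was 334 ± 95.9 in Old and 392 ± 80.7 in Cohoused Old, and C4b 308 ± 99.2 and 277 ± 38.3. Of 18 meningeal and perivascular fibroblast markers, 16 were higher in Cohoused Old and 0 were called, also adjusted over the list alone (median 0.47, adjusted p = 0.697 with an estimated correlation). Of 18 choroid plexus markers, all 18 were higher (median 0.66, adjusted p = 0.833 with an estimated correlation). Their mean log2 level was 5.93 in Cohoused Old 2 and 4.78 in Cohoused Old 4, against 4.66 in Old 2. None of the 7 lists called at the preset correlation held with an estimated correlation.

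The comparison of Cohoused Old with Cohoused Young asked how the age groups differed among cohoused mice. Mmp12, macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose from 1.38 ± 0.691 (n = 5) in Cohoused Young to 12.3 ± 9.76 (n = 5) in Cohoused Old, a log2 change of 2.15 (SE 0.40, adjusted p = 0.0486). Slc7a10, an amino acid transporter of astrocytes (ENSMUSG00000030495, chromosome 7, 35186385 to 35201114), rose from 13.4 ± 3.92 to 34.2 ± 9.38, by 1.29 (SE 0.23, adjusted p = 0.0325). Sdc3, a heparan sulfate proteoglycan of neurons (ENSMUSG00000025743, chromosome 4, 130792537 to 130826319), fell from 276 ± 49.0 to 169 ± 10.2, a log2 change of -0.69 (SE 0.11, adjusted p = 0.0325). In all 9 genes passed, 7 higher and 2 lower, among them Rps13-ps2 (0.963 ± 1.52 and 15.2 ± 8.57), Entpd4b (0.94) and Tmem181b-ps (-1.09). With only the libraries of the groups compared, with replicate number as a block or in limma without its trend 0 passed. The count was 2 in limma-voom with quality weights and 5 with a pseudocount of 0.1 or 0.5. It was 7 to 12 under the other alternatives that kept all libraries. Clec7a (adjusted p = 0.0968), Mapkapk3 (1.49, adjusted p = 0.0602), Polr2a (-0.67), Kif5c (-0.75) and C4b (1.25, adjusted p = 0.221) did not pass.

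Of 34 genes known to rise with age, 31 were higher in Cohoused Old than in Cohoused Young, with a median of 0.61; 0 were called and 17 were higher adjusted over the list alone, with H2-D1 at 0.89 and Lyz2 at 1.57 (adjusted p = 0.383 with an estimated correlation). All 22 myelin genes were higher, 0 were called and 13 were higher adjusted over the list alone, with Ermn at 0.79, Apod at 0.90 and Mobp at 0.64 (adjusted p = 0.281 with an estimated correlation). Of 26 microglia activation genes, 23 were higher, 0 were called and 5 were higher adjusted over the list alone, Itgax (1.70) among them (adjusted p = 0.442 with an estimated correlation). Of 9 genes of MHC class II antigen presentation 7 were higher, 0 were called and 5 were higher adjusted over the list alone, with H2-Eb1 at 1.35 and Cd74 at 1.45 (adjusted p = 0.533 with an estimated correlation). Of 6 blood cell markers 5 were higher and 4 passed adjusted over the list alone (adjusted p = 0.542 with an estimated correlation), and Hba-a1, a haemoglobin chain, was 412 in Cohoused Old 2 and 682 in Cohoused Old 5. The count of genes was 0 without Cohoused Young 3, Cohoused Old 1, Cohoused Old 3 or Cohoused Old 4, 1 without Cohoused Young 4, Cohoused Old 2 or Cohoused Old 5, and 2 without Cohoused Young 2 or 5. It was 81 without Cohoused Young 1, including all 9, and C4b (1.57, adjusted p = 0.0214) and Mobp (0.82, adjusted p = 0.00651) passed there.

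The age difference averaged over both housings asked which genes differed with age over all 19 libraries. Clec7a, Lyz2 and C4b were among the genes higher in the old groups. Clec7a, a microglial receptor (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779), rose (adjusted p = 0.00248), from 0.586 ± 0.381 in Young and 0.932 ± 1.39 in Cohoused Young to 5.25 ± 2.96 in Old and 5.18 ± 1.87 in Cohoused Old. Lyz2, lysozyme (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), rose by 1.70 (SE 0.28, adjusted p = 0.00580), and C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) by 1.47 (SE 0.25, adjusted p = 0.00954). Mmp12 rose by 1.56, and Cybb, a subunit of the NADPH oxidase (adjusted p = 0.0419), and Cst7, cystatin F (adjusted p = 0.0422), also rose. Cst7 was listed at 0 in all 5 Young libraries. Klk6 rose by 1.84 (adjusted p = 0.00580), Apod by 1.07 (adjusted p = 0.00271), Ide by 0.82 (adjusted p = 0.000177) and Mid1 by 1.14. Fos fell by 1.61 (adjusted p = 0.00987) and Junb by 0.72 (adjusted p = 0.0263), and Egr1 had a change of -0.65 (adjusted p = 0.0539). In all 58 genes passed, 44 higher and 14 lower. The other lower genes named by the rule were Tmem181b-ps (-1.26, adjusted p = 6.82e-05), Olfr648 (-1.24), Wdfy1 (-0.88), Tmem181a (-0.87), C2cd4c (-0.75), Kank1 (-0.62), Tmem100 (-0.54), Magi2, a synaptic scaffold (-0.45), Arpp21 (-0.44) and Sdc3 (-0.38), and Entpd4 (0.82) and Entpd4b (0.90) were higher.

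**Figure D2:**
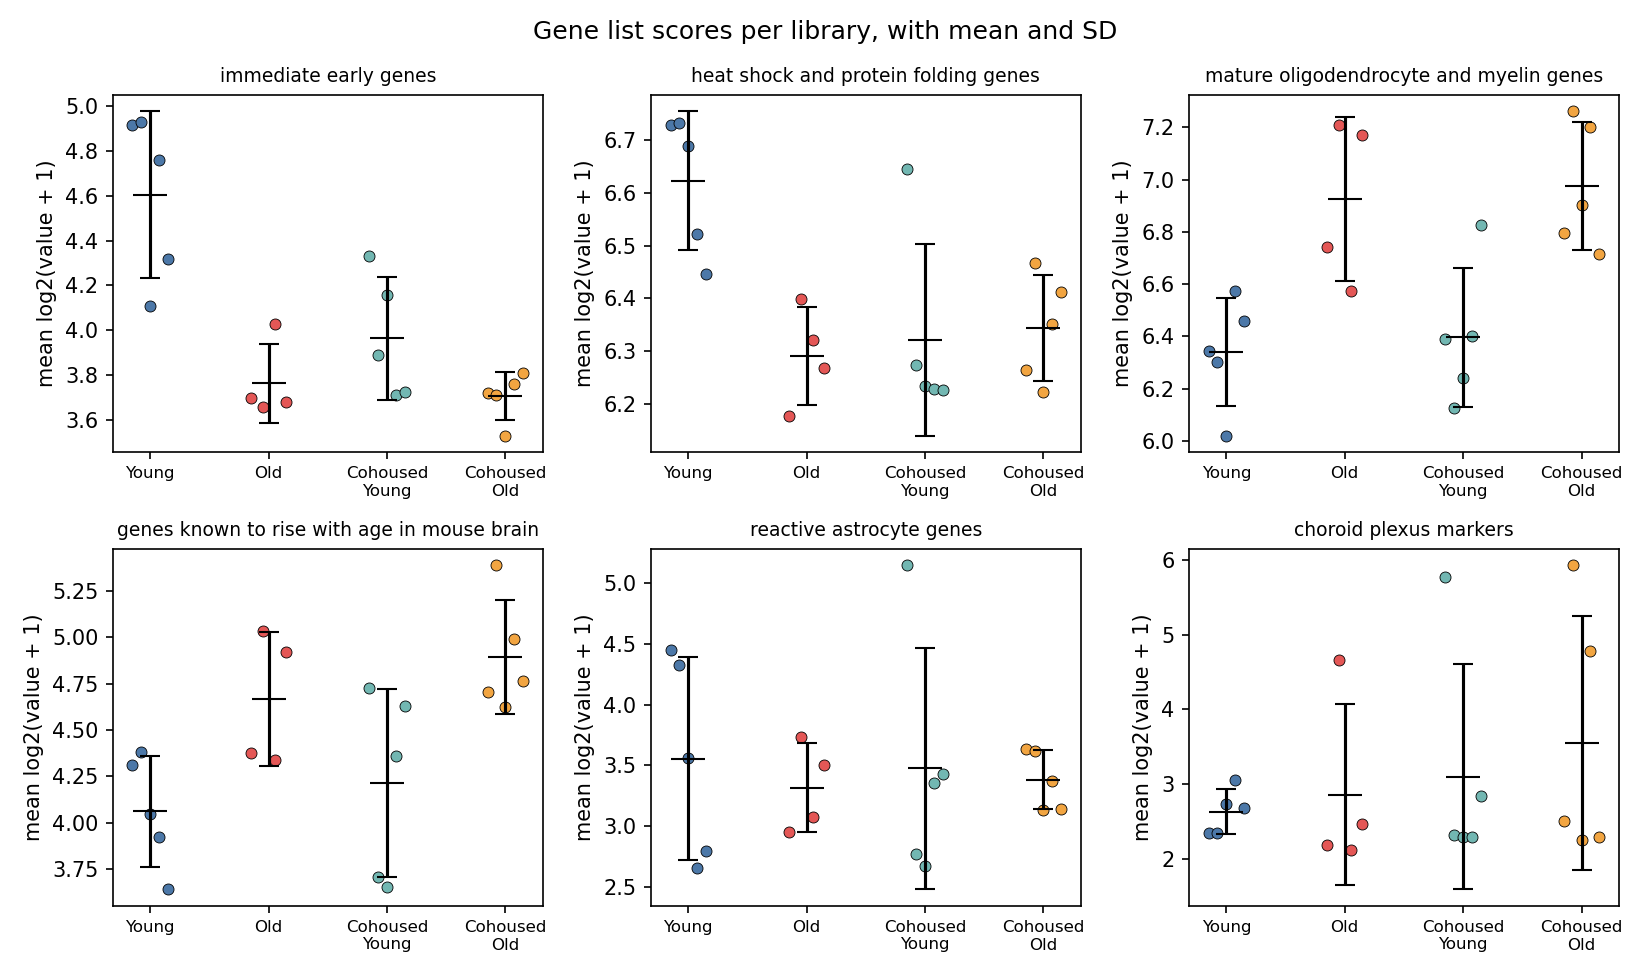
Each panel plots the mean log2(value + 1) over the members of a gene list, with a point per library and the mean and SD of the 4 groups. The choroid plexus score was 5.77 in Cohoused Young 2 and 5.93 in Cohoused Old 2, and the immediate early gene score 4.93 in Young 5 and 3.66 in Old 2.

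All 22 myelin genes were higher in the old groups, with a median of 0.50; 6 were called and 18 were higher adjusted over the list alone, among them Mobp (0.69, adjusted p = 0.0130) and Hapln2 (0.78, adjusted p = 0.0141). All 23 immediate early genes were lower, with a median of -0.56; Fos and Junb were called and 15 were lower adjusted over the list alone. Of 22 delayed activity-regulated genes 21 were lower, 0 were called and 9 were lower adjusted over the list alone, with Rgs4 at -0.50 and Nptx2, a secreted synaptic protein, at -0.71. The adjusted p with an estimated correlation was 0.0423 for the myelin genes and 0.0345 for each of the activity lists. Of 5 measured markers of T, B and plasma cells 4 were higher, 1 was called, Ighm, an immunoglobulin heavy chain (1.13, adjusted p = 0.0153), and 3 were higher adjusted over the list alone. Their adjusted p was 0.0488 with an estimated correlation and 0.0734 without Cohoused Young 1. Of 34 genes known to rise with age 32 were higher, 8 were called and 21 were higher adjusted over the list alone. Of 26 microglia activation genes 23 were higher, 5 were called and 11 were higher adjusted over the list alone. Both lists had adjusted p = 0.0750 with an estimated correlation. Of 20 genes of MHC class I antigen presentation 18 were higher, 1 was called, H2-D1 (0.72, adjusted p = 0.0263), and 4 were higher adjusted over the list alone (adjusted p = 0.170 with an estimated correlation). Library totals gave 58 higher and 8 lower genes. The count was 158 without Cohoused Young 1, including all 58, 18 without Young 4 and 5, 20 without Old 4, 32 without Young 5 or Cohoused Old 4, 34 without Cohoused Young 3, 35 without Young 4 or Cohoused Old 2, 37 without Young 3 or Cohoused Old 3, and 38 without Cohoused Young 4 or Old 2. With a weight per library it was 99.

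The interaction of age and cohousing asked whether the age difference was unlike in cohoused mice and mice that were not cohoused. Plin4 was the 1 gene that passed, with a log2 difference of -2.83 (SE 0.43, adjusted p = 0.0244): it was 15.3 ± 8.91 in Young and 77.2 ± 16.2 in Old, but 69.1 ± 20.6 in Cohoused Young and 50.7 ± 17.3 in Cohoused Old. Slc7a10 (1.51), Stx8 (1.15, adjusted p = 0.103), Sgk3 (-1.04), Mapkapk3 (2.08), Rps13-ps2, Ipo11 (1.21), Sfpq (0.89), Luc7l (0.79) and Sh2b2 (-1.43) did not pass. Of 23 immediate early genes 21 had a difference above 0, 0 were called and 2 passed adjusted over the list alone, Egr4 (1.06) and Junb (0.98), with adjusted p = 0.387 with an estimated correlation. Of 23 heat shock and protein folding genes 20 had a difference above 0 and 6 passed adjusted over the list alone (adjusted p = 0.106 with an estimated correlation). Of 100 regroupings of the libraries 5 gave as many genes, the labelled groups included, and 0 genes passed without Cohoused Young 2, 4 or 5, Young 2, 3, 4 or 5, Cohoused Old 1 or 5, or Old 1, 2 or 4. With replicate number as a block, library number as a term, a weight per library or limma-voom with quality weights 0 passed. Plin4 still passed with the other scalings, filters and pseudocounts.

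The contrasts were also compared across all genes, which are not independent replicates. The log2 changes of Old vs Young and Cohoused Young vs Young, which share the Young group, had a correlation of 0.50, where unchanged simulated groups gave 0.42, and 39 of 100 simulations were as high. The changes of Old vs Young and Cohoused Old vs Cohoused Young, which share no group, had a correlation of 0.22, with 24 of 100 simulations as high. In these contrasts 4 genes were called higher in both, where 0.0063 would be expected by chance for independent genes, and 1 was called lower in both. Of these the naming rule gave Entpd4b, higher, and Tmem181b-ps, lower. Both belong to the pairs of near-identical copies, for which a colony or substrain difference was not tested. Cohoused Young vs Young and Cohoused Old vs Old had a correlation of -0.016. The correlation of Old vs Young with Cohoused Old vs Old was -0.42 and that of Cohoused Young vs Young with Cohoused Old vs Cohoused Young -0.45, where simulated groups gave -0.54 and -0.50.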

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

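Every test of an explanation in this part was chosen only after the result it concerns was seen.

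Cohoused Young 1 had the values of the old groups for many of the genes that were higher or lower with age. Its C4b was 284, Klk6 10.6, Apod 391, Clec7a 3.27 and Tmem181a 163, and its Lyz2 was 36.0 where the next Cohoused Young library had 11.6. Gm13301, a predicted gene outside the naming rule, was 24.2 in this library, 1.25 to 4.83 in the other Cohoused Young, 16.4 to 29.4 in the old groups and at most 0.807 in Young. Other genes lay with its own label. Slc7a10 was 9.95, near the lowest other Cohoused Young value of 10.6 and below all libraries of the other groups, of which Cohoused Old had 25.4 to 46.7. Rps13-ps2 was 7.9e-08, where the other Cohoused Young had at most 3.47 and Cohoused Old 4.06 to 24.5. Both genes are named because they passed in Cohoused Old vs Cohoused Young with this library counted under its label. That choice favours genes that go with the label, so they are no separate support for it. Without this library 81 genes passed in that contrast, of which 9 passed with it.

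Of 102 age genes chosen without Cohoused Young 1 and without a called neighbour, 84.3% lay nearer to the old mean in this library. The other libraries were each scored on their own set of 11 to 40 genes, chosen the same way. The share was 0 to 52.5% in the other young libraries and 45.7 to 100% in the old ones. A variant of strain or colony that moves only genes with a called neighbour could not alone account for 84.3%, since the highest other young library lay at 52.5%. A variant that moves single genes or genes further apart was not tested and stays open. A wrong label was then tested on 100 genes that set Cohoused Young apart, added after the first test was seen: the library lay nearer to the Cohoused Young mean for 18%, against 36 to 57% in the others of that label and 6 to 40% in the other groups. A wrong label could therefore account for it, although both ranges overlap and both criteria are loose. On the 52 age genes with a called neighbour, 84.6% lay nearer to the old mean in this library. Scored on their own sets, the other Cohoused Young had 8.33 to 23.1% and the old libraries 83.3 to 100%. The other Cohoused Young thus did not share this pattern. A response of this mouse alone to cohousing was not tested and stays open.

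Immediate early genes had lower means in both Old and Cohoused Young than in Young, but in Cohoused Young vs Young neither Fos (adjusted p = 0.157) nor Egr1 (adjusted p = 0.117) passed, and the list did not with an estimated correlation (adjusted p = 0.0874). Young 4 and 5 had high Timp1 (18.6 and 12.8), a gene of tissue reaction. They were not the whole cause of the lower medians, since without them the median nearer to 0 of the contrasts was -0.57. That criterion also rested on the list call at the preset correlation, and without them 0 genes passed in Cohoused Young vs Young. A different time of day at collection could not be told from none, as a score of clock genes differed from Young with exact permutation p = 0.397 for Old and p = 0.167 for Cohoused Young.

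Reactive astrocyte genes were high in single libraries, with a mean log2 level of 5.15 in Cohoused Young 2, 4.45 in Young 4 and 4.33 in Young 5. Over 19 libraries their level had a Spearman rho of 0.45 with that of choroid plexus markers (permutation p = 0.0543, adjusted p = 0.109 over 2 measures) and a Pearson r of 0.46 (permutation p = 0.0462, adjusted p = 0.0924), or 0.12 without Cohoused Old 2 and Cohoused Young 2. Choroid plexus as the whole cause was excluded for Cohoused Young 2, at a choroid plexus level of 5.77, since Cohoused Old 2 (5.93), Cohoused Old 4 (4.78) and Old 2 (4.66) had reactive levels of 3.62, 3.37 and 3.74, and for Young 4 and 5, whose choroid plexus level of 2.35 lay below the 2.68 to 3.06 of the other Young. With the estimated reads rho was 0.012 (permutation p = 0.963, adjusted p = 0.963) and r 0.053, or 0.25 without Cohoused Old 5 and Young 1. The other 4 libraries of similar depth had reactive levels of 2.65 to 3.50 with an SD of 0.407, which with a bootstrap interval of rho from -0.47 to 0.48 neither shows nor excludes depth, and no biological explanation was tested.

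Of 276 group measures, 21 had a library that stood apart by Dixon's test, which is 7.61%. The limits used flag a measure by chance at a rate of about 0.05, and no correction was made for the number of measures. Many of the 21 could therefore arise by chance, and some measures overlap. Plin4 was 30.6 in Young 1 with the next Young library at 15.02. Tmem181a was 343 in Young 3 with the next at 305. Arc, a synaptic activity gene, was 251 in Young 2 with the next at 151. Cln6 was 11.9 in Old 1 with the next Old library at 15.8. Olfr648 was 22.4 in Old 3 with the next at 18.9, and Tmem100 10.5 with the next at 8.63. Arpp21 was 188 in Old 2 with the next at 134.

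Ttr was 1841 in Old 2 with the next at 35.8, and 7931 in Cohoused Young 2 with the next at 84.5. The choroid plexus level, to which Ttr belongs, was 4.66 in Old 2 with the next at 2.47, and 5.77 in Cohoused Young 2 with the next at 2.84. In Cohoused Old 2, Tmem181b-ps was 35.7 with the next at 47.6, Egr4 6.10 with the next at 10.3, Cybb 15.4 with the next at 3.16 and C2cd4c 5.67 with the next at 9.12. The level of T, B and plasma cell markers was 2.35 in Cohoused Old 2 with the next at 1.74. Immediate early genes had a level of 4.03 in Old 3 with the next Old library at 3.70. Heat shock and protein folding genes had a level of 6.65 in Cohoused Young 2 with the next at 6.27. Neuromodulator receptor genes were at 3.86 in Old 1 with the next at 3.67, and cholesterol biosynthesis genes at 5.36 in Cohoused Old 5 with the next at 5.47.

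In the interaction of age and cohousing Plin4 had -2.83, and 9 lists were called at the preset correlation, none of which held with an estimated correlation. Their medians were 0.53 for immediate early genes, 0.24 for delayed activity-regulated genes, 0.36 for heat shock and protein folding genes, 1.12 for blood cell markers, 0.17 for nuclear oxidative phosphorylation genes, 0.33 for mitochondrially encoded genes, 0.21 for ribosomal protein genes, -0.17 for astrocyte markers and -0.56 for glucocorticoid-responsive genes.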

How the results depend on the processing

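The tests chosen only after the result was seen were limma-voom on estimated reads with and without library quality weights, a weight per library, the fits without Cohoused Young 1 and 2, without Young 4 and 5 or without Cohoused Young 1 and with weights, quantile scaling of the list tests and of the similarities, the exact permutation of list scores, and the similarities without Cohoused Young 1. The size factors and the count-based test that had been planned as alternatives were not run, because the deposited values are not read counts. At the estimated depth of 2.243 to 9.259 M reads, a simulated change of 1.5-fold was found for 26.8% of genes in Old vs Young, so most changes of that size were below what the comparison could show. The count of 0 in Cohoused Old vs Old held under every alternative and with each of its 9 libraries left out. Where no cause is given for a value below, the cause was not tested.

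Gene counts moved by less than 1.5 times in all 6 comparisons under quantile scaling, library totals, either filter, the choroid plexus term and limma-voom on estimated reads. In Cohoused Old vs Cohoused Young the 9 genes became 0 in limma without its trend, and 5 with a pseudocount of 0.1 or of 0.5, all 5 among the 9. With only the libraries of the groups compared, which leaves fewer samples for the error, Cohoused Young vs Young and Cohoused Old vs Cohoused Young each had 0. The interaction had 2 genes in limma without its trend, 1 of them Plin4. With the library number as a linear term Old vs Young had 9 genes, all among the 22, and Cohoused Young vs Young and the interaction had 0. A weight per library gave 67 genes in Old vs Young, including all 22, 99 in the age average and 0 in the interaction. Limma-voom with library quality weights gave 59 in Old vs Young, 0 in Cohoused Young vs Young, 2 in Cohoused Old vs Cohoused Young and 0 in the interaction.

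With replicate number as a replicate block, Old vs Young had 13 genes, Cohoused Young vs Young 1, Cohoused Old vs Cohoused Young 0 and the interaction 0, while the age average had 42. The numbers in the labels did not pair the libraries: the correlation of residuals ranged from -0.18 to 0.20 over 27 pairs with the same number, and 4 of 19 libraries were closest to a library of their own number.

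Without Cohoused Young 1 and with weights, 30 genes passed in Cohoused Young vs Young, 47 in Cohoused Old vs Cohoused Young, 173 in the age average and 0 in the interaction. Without Cohoused Young 1 and 2 the counts were 52, 79, 130 and 2. Without Young 4 and 5, Old vs Young had 4 genes, all among the 22, Cohoused Young vs Young 0, the age average 18, all among the 58, and the interaction 0. Leaving out each library in turn gave 7 to 21 genes in Old vs Young, 1 to 32 in Cohoused Young vs Young, 0 to 81 in Cohoused Old vs Cohoused Young, 20 to 158 in the age average and 0 to 1 in the interaction. Among the named genes past the threshold, 3 of 17 in Old vs Young, 1 of 9 in Cohoused Young vs Young, 0 of 6 in Cohoused Old vs Cohoused Young, 12 of 24 in the age average and 0 of 1 in the interaction passed without each library in turn.

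The changes of sign were in genes that passed the threshold under neither setting, given here as log2 changes. For Gfap the change became 0.033 in the interaction with quantile scaling, and -0.12 in Cohoused Old vs Old with the replicate block. The choroid plexus term turned it to -0.065 in Cohoused Young vs Young and -0.18 in Cohoused Old vs Old, and turned Npas4 to 0.11 in Cohoused Old vs Old and Ttr to -0.075 in the interaction. A weight per library turned Gfap to -0.39 in Cohoused Young vs Young and 0.41 in the interaction, and Bdnf to 0.013 in the age average. Limma-voom with quality weights gave -0.31 and 0.35 for Gfap and 0.0063 for Bdnf in the same comparisons. Without Cohoused Young 1 and with weights, C4b was -0.15 in Cohoused Young vs Young and 0.032 in the interaction, and Gfap -0.44 in Cohoused Young vs Young, 0.022 in Cohoused Old vs Cohoused Young and 0.46 in the interaction. There Bdnf was 0.056 in the age average and Npas4 -0.071 in the interaction. Without Cohoused Young 1 and 2, C4b was -0.023, Gfap -0.37 and Ttr -0.82 in Cohoused Young vs Young. Gfap was then 0.044 in Cohoused Old vs Cohoused Young and 0.39 in the interaction, and Bdnf 0.015 in the age average. Without Young 4 and 5, Gfap was 0.17 and Ttr -0.0035 in Old vs Young, Npas4 0.11 in Cohoused Young vs Young and -0.15 in the interaction, and Bdnf 0.034 in the age average. With each library left out, Ttr ranged from -0.91 to 1.64 in Old vs Young, -0.31 to 1.87 in Cohoused Young vs Young and -0.65 to 2.09 in the interaction. Gfap ranged from -0.35 to 0.45 in Cohoused Young vs Young, -0.43 to 0.37 in the interaction, -0.77 to 0.030 in Cohoused Old vs Cohoused Young and -0.072 to 0.15 in Cohoused Old vs Old. In Cohoused Old vs Old C4b ranged from -0.30 to 0.053, Arc from -0.40 to 0.073 and Npas4 from -0.26 to 0.10, and Bdnf ranged from -0.099 to 0.0047 in the age average.

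Of the 68 calls of a gene list, 59 were lost with an estimated correlation, with these adjusted p. Genes known to rise with age gave 0.202 in Old vs Young, 0.833 in Cohoused Old vs Old, 0.383 in Cohoused Old vs Cohoused Young and 0.0750 in the age average. Genes known to fall with age gave 0.202 in Old vs Young and 0.170 in the age average. Complement genes gave 0.300 in Old vs Young, 0.622 in Cohoused Old vs Cohoused Young and 0.192 in the age average. MHC class I genes gave 0.368 in Old vs Young, 0.533 in Cohoused Old vs Cohoused Young and 0.170 in the age average. MHC class II genes gave 0.368 in Old vs Young, 0.533 in Cohoused Old vs Cohoused Young and 0.170 in the age average. Microglia activation genes gave 0.202 in Old vs Young, 0.442 in Cohoused Old vs Cohoused Young and 0.0750 in the age average. Homeostatic microglia markers gave 0.300 in Old vs Young, 0.533 in Cohoused Old vs Cohoused Young and 0.158 in the age average. T, B and plasma cell markers gave 0.189 in Old vs Young and 0.281 in Cohoused Old vs Cohoused Young. Astrocyte markers gave 0.300 in Old vs Young, 0.319 in Cohoused Young vs Young and 0.433 in the interaction. Myelin genes gave 0.155 in Old vs Young and 0.281 in Cohoused Old vs Cohoused Young. Ependymal markers gave 0.579 in Old vs Young and 0.667 in the age average. Glucocorticoid-responsive genes gave 0.202 in Old vs Young, 0.319 in Cohoused Young vs Young, 0.697 in Cohoused Old vs Old, 0.533 in Cohoused Old vs Cohoused Young and 0.168 in the interaction. Oxidative phosphorylation genes gave 0.789 in Old vs Young, 0.866 in Cohoused Young vs Young and 0.978 in the interaction. Immediate early genes gave 0.0874 in Cohoused Young vs Young, 0.542 in Cohoused Old vs Cohoused Young and 0.387 in the interaction. Circadian clock genes gave 0.864 in Cohoused Young vs Young. Mitochondrially encoded genes gave 0.866 in Cohoused Young vs Young and 0.978 in the interaction. Ribosomal protein genes gave 0.866 in Cohoused Young vs Young, 0.772 in Cohoused Old vs Cohoused Young and 0.978 in the interaction. Interferon-stimulated genes gave 0.811 in Cohoused Old vs Old and 0.720 in the age average. Neuromodulator receptor genes gave 0.697 in Cohoused Old vs Old. Choroid plexus markers gave 0.833 in Cohoused Old vs Old. Meningeal fibroblast markers gave 0.697 in Cohoused Old vs Old. Blood cell markers gave 0.811 in Cohoused Old vs Old, 0.542 in Cohoused Old vs Cohoused Young and 0.827 in the interaction. Heat shock genes gave 0.158 in the age average and 0.106 in the interaction. Cholesterol biosynthesis genes gave 0.544 in the age average. Delayed activity genes gave 0.361 in the interaction.

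By exact permutation of the list scores, 37 of 44 calls had an adjusted p above the threshold. The smallest exact p that the groups allow is 0.00794, which over 41 lists becomes 0.325 for a list that reaches it alone. Delayed activity and glucocorticoid-responsive genes in Cohoused Young vs Young, neuromodulator receptor genes in Cohoused Old vs Old and T, B and plasma cell markers in Cohoused Old vs Cohoused Young had this smallest p, so that their adjusted p speaks neither for nor against them. Immediate early genes gave 0.0723 in Old vs Young, 0.325 in Cohoused Young vs Young and 0.390 in Cohoused Old vs Cohoused Young. Genes known to rise with age gave 0.148 in Old vs Young, 0.857 in Cohoused Old vs Old and 0.390 in Cohoused Old vs Cohoused Young. Genes known to fall with age gave 0.163 in Old vs Young. MHC class I genes gave 0.209 in Old vs Young and 0.390 in Cohoused Old vs Cohoused Young. Homeostatic microglia markers gave 0.175 in Old vs Young and 0.390 in Cohoused Old vs Cohoused Young. Astrocyte markers gave 0.130 in Old vs Young and 0.325 in Cohoused Young vs Young. Ependymal markers gave 0.383 in Old vs Young. Heat shock genes gave 0.0723 in Old vs Young and 0.325 in Cohoused Young vs Young. Oxidative phosphorylation genes gave 0.651 in Old vs Young and 0.843 in Cohoused Young vs Young. Delayed activity genes gave 0.163 in Cohoused Young vs Young. Glucocorticoid-responsive genes gave 0.163 in Cohoused Young vs Young, 0.795 in Cohoused Old vs Old and 0.390 in Cohoused Old vs Cohoused Young. Circadian clock genes gave 0.372 in Cohoused Young vs Young. Mitochondrially encoded genes gave 0.843 in Cohoused Young vs Young. Ribosomal protein genes gave 0.843 in Cohoused Young vs Young and 0.759 in Cohoused Old vs Cohoused Young. Interferon-stimulated genes gave 0.795 in Cohoused Old vs Old. Neuromodulator receptor genes gave 0.325 in Cohoused Old vs Old. Choroid plexus markers gave 0.857 in Cohoused Old vs Old. Meningeal fibroblast markers gave 0.795 in Cohoused Old vs Old. Blood cell markers gave 0.857 in Cohoused Old vs Old and 0.526 in Cohoused Old vs Cohoused Young. Complement genes gave 0.461 in Cohoused Old vs Cohoused Young. MHC class II genes gave 0.390 in Cohoused Old vs Cohoused Young. Microglia activation genes gave 0.390 in Cohoused Old vs Cohoused Young. T, B and plasma cell markers gave 0.325 in Cohoused Old vs Cohoused Young. Myelin genes gave 0.390 in Cohoused Old vs Cohoused Young.

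Quantile scaling ended 10 of the 68 list calls. Oxidative phosphorylation genes gave 0.156 in Old vs Young. Mitochondrially encoded genes gave 0.286 in Cohoused Young vs Young and 0.80 in the interaction. Complement genes gave 0.0561 in Cohoused Old vs Cohoused Young. T, B and plasma cell markers gave 0.0586 in Cohoused Old vs Cohoused Young. Glucocorticoid-responsive genes gave 0.0661 in Cohoused Old vs Cohoused Young. Interferon-stimulated genes gave 0.0711 in the age average. Ependymal markers gave 0.0655 in the age average. Cholesterol biosynthesis genes gave 0.111 in the age average. Astrocyte markers gave 0.0917 in the interaction. The replicate block ended 2. Ependymal markers gave 0.0741 in Old vs Young. Cholesterol biosynthesis genes gave 0.0535 in the age average. The choroid plexus term, which removes the markers' own level by construction, ended 9. Genes known to rise with age gave 0.462 in Cohoused Old vs Old. Interferon-stimulated genes gave 0.451 in Cohoused Old vs Old and 0.0785 in the age average. Neuromodulator receptor genes gave 0.0951 in Cohoused Old vs Old. Choroid plexus markers gave 0.895 in Cohoused Old vs Old. Blood cell markers gave 0.170 in Cohoused Old vs Old. Glucocorticoid-responsive genes gave 0.0553 in Cohoused Old vs Old. Complement genes gave 0.146 in Cohoused Old vs Cohoused Young. Ependymal markers gave 0.0764 in the age average. Limma-voom on estimated reads ended 2. Complement genes gave 0.0557 in Cohoused Old vs Cohoused Young. Ependymal markers gave 0.0878 in the age average. A weight per library left cholesterol biosynthesis genes at 0.0534 in the age average, and quality weights left them at 0.0516.

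Without Cohoused Young 1 and with weights 4 of 45 list calls were lost. Astrocyte markers gave 0.124 in Cohoused Young vs Young and 0.131 in the interaction. T, B and plasma cell markers gave 0.0566 in Cohoused Old vs Cohoused Young. Cholesterol biosynthesis genes gave 0.102 in the age average. Without Cohoused Young 1 and 2 the lost calls were 3 of 45. Mitochondrially encoded genes gave 0.284 in Cohoused Young vs Young and 0.234 in the interaction. Cholesterol biosynthesis genes gave 0.101 in the age average. Without Young 4 and 5, 15 of 49 were lost and oxidative phosphorylation genes in Old vs Young turned to a median of 0.022. T, B and plasma cell markers gave 0.0655 in Old vs Young. Astrocyte markers gave 0.0971 in Old vs Young, 0.0509 in Cohoused Young vs Young and 0.103 in the interaction. Ependymal markers gave 0.486 in Old vs Young and 0.169 in the age average. Oxidative phosphorylation genes gave 0.743 in Old vs Young, 0.295 in Cohoused Young vs Young and 0.539 in the interaction. Circadian clock genes gave 0.143 in Cohoused Young vs Young. Ribosomal protein genes gave 0.280 in Cohoused Young vs Young and 0.584 in the interaction. Cholesterol biosynthesis genes gave 0.310 in the age average. Delayed activity genes gave 0.158 in the interaction. Blood cell markers gave 0.0896 in the interaction. Mitochondrially encoded genes gave 0.0598 in the interaction.

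Leaving out each library in turn ended these list calls, given with their range of adjusted p. MHC class II genes ranged from 0.00292 to 0.0843 in Old vs Young (highest without Old 2) and 6.39e-04 to 0.105 in Cohoused Old vs Cohoused Young (highest without Cohoused Old 2). T, B and plasma cell markers ranged from 0.0123 to 0.116 in Old vs Young (highest without Old 2) and 0.00497 to 0.0537 in Cohoused Old vs Cohoused Young (highest without Cohoused Old 2). Astrocyte markers ranged from 0.0217 to 0.117 in Old vs Young (highest without Old 2), 0.00257 to 0.176 in Cohoused Young vs Young (highest without Cohoused Young 1) and 0.00528 to 0.189 in the interaction (highest without Cohoused Young 1). Blood cell markers ranged from 2.38e-05 to 0.350 in Cohoused Old vs Old (highest without Cohoused Old 5), 1.20e-05 to 0.0837 in Cohoused Old vs Cohoused Young (highest without Cohoused Old 5) and 3.38e-04 to 0.211 in the interaction (highest without Cohoused Old 5). Cholesterol biosynthesis genes ranged from 0.00636 to 0.110 in the age average (highest without Young 5). Choroid plexus markers ranged from 2.37e-07 to 0.844 in Cohoused Old vs Old (highest without Cohoused Old 2). Circadian clock genes ranged from 0.00338 to 0.0793 in Cohoused Young vs Young (highest without Cohoused Young 5). Complement genes ranged from 0.00232 to 0.271 in Cohoused Old vs Cohoused Young (highest without Cohoused Old 2). Ependymal markers ranged from 0.00691 to 0.194 in Old vs Young (highest without Old 2) and 3.73e-04 to 0.104 in the age average (highest without Cohoused Old 2). Genes known to fall with age ranged from 0.00556 to 0.141 in Old vs Young (highest without Old 1) and 0.00811 to 0.104 in the age average (highest without Cohoused Young 5). Genes known to rise with age ranged from 5.06e-05 to 0.505 in Cohoused Old vs Old (highest without Cohoused Old 2). Glucocorticoid-responsive genes ranged from 0.00128 to 0.0657 in Cohoused Young vs Young (highest without Cohoused Young 5), 0.00417 to 0.157 in Cohoused Old vs Old (highest without Old 2) and 0.0116 to 0.497 in Cohoused Old vs Cohoused Young (highest without Cohoused Young 5). Interferon-stimulated genes ranged from 0.00244 to 0.425 in Cohoused Old vs Old (highest without Cohoused Old 2) and 1.55e-05 to 0.112 in the age average (highest without Cohoused Young 4). Mitochondrially encoded genes ranged from 5.78e-06 to 0.225 in Cohoused Young vs Young (highest without Cohoused Young 2) and 1.44e-04 to 0.200 in the interaction (highest without Cohoused Young 2). Neuromodulator receptor genes ranged from 0.0194 to 0.321 in Cohoused Old vs Old (highest without Old 1). Oxidative phosphorylation genes ranged from 0.00440 to 0.712 in Old vs Young (highest without Old 1), 2.40e-09 to 0.291 in Cohoused Young vs Young (highest without Cohoused Young 5) and 4.32e-06 to 0.467 in the interaction (highest without Cohoused Young 5). Ribosomal protein genes ranged from 1.11e-12 to 0.0657 in Cohoused Young vs Young (highest without Cohoused Young 5), 1.23e-11 to 0.497 in Cohoused Old vs Cohoused Young (highest without Cohoused Young 5) and 4.79e-08 to 0.266 in the interaction (highest without Cohoused Young 5).

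The genes called in either contrast were picked by their calls in the same contrasts, so values over them are no separate test of similarity. Over these genes, the correlation of log2 changes was 0.72 for Old vs Young with Cohoused Young vs Young and 0.75 for Old vs Young with Cohoused Old vs Cohoused Young. It was -0.27 for Cohoused Young vs Young with Cohoused Old vs Old, -0.052 for Old vs Young with Cohoused Old vs Old, and -0.16 for Cohoused Young vs Young with Cohoused Old vs Cohoused Young. With the shared group divided between the contrasts, which removes their common libraries, the values over all genes were 0.19 for Old vs Young with Cohoused Young vs Young, 0.024 for Old vs Young with Cohoused Old vs Old, and 0.034 for Cohoused Young vs Young with Cohoused Old vs Cohoused Young.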

Other observations

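The regroupings of libraries and the criteria read from them were chosen only after the results were seen.

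Genes of antigen presentation and resident microglia were mostly higher in the old groups in the age average. Of 9 genes of MHC class II antigen presentation 8 were higher, 1 was called, Ctss, a lysosomal protease (0.59, adjusted p = 0.0419), and 4 were higher adjusted over the list alone, with Cd74 at 1.21 and H2-Aa at 0.93 (adjusted p = 0.170 with an estimated correlation). Of 16 homeostatic microglia markers 15 were higher and 1 was called (adjusted p = 0.158 with an estimated correlation). Of 17 complement genes 14 were higher, 1 was called, C4b, and 4 were higher adjusted over the list alone (adjusted p = 0.192 with an estimated correlation). All 13 ependymal cell markers were higher and 0 were called (median 0.28, adjusted p = 0.667 with an estimated correlation). Their highest levels, 3.07 in Cohoused Old 2, 2.77 in Cohoused Old 4, 2.67 in Old 2 and 2.64 in Cohoused Young 2, were in the libraries with the highest choroid plexus level. At the preset correlation the ependymal list had adjusted p = 0.0764 with the choroid plexus term and 0.104 without Cohoused Old 2, and lost its call also without Cohoused Old 4, Old 2 or Cohoused Young 5. Of 33 interferon-stimulated genes 25 were higher and 0 were called (adjusted p = 0.720 with an estimated correlation), and the call was lost without Cohoused Young 4 (0.112), Cohoused Young 3 or 5, Young 3, Cohoused Old 2 or Old 4. Of 22 cholesterol biosynthesis genes 18 were lower (median -0.06, adjusted p = 0.544 with an estimated correlation), and of 27 genes known to fall with age 17 were lower (adjusted p = 0.170 with an estimated correlation). The cholesterol list lost its call without Young 5 (0.110), Young 1 or 4, Cohoused Young 2 or 5, Cohoused Old 2 or 5, or Old 2, and the other list without Cohoused Young 5 (0.104), Cohoused Old 3 or 5, or Old 1 or 3.

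Markers of the neuronal layers had medians near 0 for age. In the age average the median was 0.14 for 14 dentate granule cell markers, 0.16 for 11 CA1 pyramidal cell markers, 0.05 for 16 CA2 and CA3 pyramidal cell markers and 0.05 for 19 GABAergic interneuron markers, and -0.03 for 21 markers of neurogenesis and immature neurons. It was -0.02 for 27 glutamate receptor and postsynaptic genes and -0.09 for 21 presynaptic vesicle genes. With all libraries none of these lists was called in any contrast, although without Cohoused Young 1 dentate granule cell markers were called in Cohoused Old vs Cohoused Young (median 0.21, adjusted p = 0.0466, or 0.719 with an estimated correlation). The same held with all libraries for markers of oligodendrocyte precursors (0.05), endothelial cells (-0.02), pericytes and smooth muscle (-0.10), perivascular and meningeal macrophages (-0.09), thalamus and habenula (0.04), and cortex and striatum (0.07), and for genes of reactive astrocytes (-0.13), inflammatory cytokines (-0.05) and senescence (-0.07).

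In Cohoused Young vs Young, 39 of 46 nuclear oxidative phosphorylation genes and 11 of 12 mitochondrially encoded genes were lower, with medians of -0.18 and -0.29 (adjusted p = 0.866 with an estimated correlation for each). Of 18 circadian clock genes 13 were higher, with a median of 0.29 (adjusted p = 0.864 with an estimated correlation), and of 17 astrocyte markers 15 were higher (adjusted p = 0.319 with an estimated correlation). At the preset correlation the oxidative phosphorylation list had adjusted p = 0.291 without Cohoused Young 5, and the mitochondrially encoded list 0.225 without Cohoused Young 2, whose level was 10.8 where all other libraries had 11.4 to 12.2. The clock list had 0.0793 without Cohoused Young 5 and lost its call also without Young 1 or Cohoused Young 4, and the astrocyte list had 0.176 without Cohoused Young 1 and lost its call also without Cohoused Young 5. In Cohoused Old vs Old, 25 of 33 interferon-stimulated genes were higher (median 0.26), all 6 blood cell markers were higher (0.79), and 22 of 28 neuromodulator receptor genes were lower (-0.09). With an estimated correlation the adjusted p was 0.811, 0.811 and 0.697. At the preset correlation the interferon list reached 0.425 without Cohoused Old 2 and lost its call also without Old 1 or 3. The blood cell list reached 0.350 without Cohoused Old 5 and lost its call also without Cohoused Old 2, Old 1 or Old 3, and the neuromodulator list reached 0.321 without Old 1 and lost its call also without Old 3 or Cohoused Old 2, 4 or 5.

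The libraries were regrouped at random to see how often as many genes were called, with the labelled grouping counted among 100. In Old vs Young 1 of 100 groupings gave as many genes, 22 with the labels and at most 4 otherwise. In the age average 1 of 100 did, 58 with the labels and at most 1 otherwise. This is the lowest share that 100 groupings allow, so that chance was unlikely in both but not excluded. In Cohoused Old vs Cohoused Young 2 of 100 did, 9 with the labels and at most 19 otherwise. This lay under 5 of 100, but another grouping gave more genes than the labels, so that chance was not excluded. In Cohoused Young vs Young 5 did, 10 with the labels and at most 86 otherwise, and in the interaction 5, 1 with the labels and at most 2 otherwise, so that chance was not excluded. In Cohoused Old vs Old, with 0 genes, all 100 did.

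Calls of gene lists at the preset correlation were no more frequent than chance allows in any contrast. As many lists were called in 12 of 100 groupings for Old vs Young (16 with the labels, at most 19 otherwise), 56 for Cohoused Young vs Young (9 and 22) and 53 for Cohoused Old vs Old (7 and 21). It was 32 for Cohoused Old vs Cohoused Young (12 and 21), 16 for the age average (15 and 21) and 51 for the interaction (9 and 23). The counts of myelin, activity and microglia genes are for this reason given as measured, and the lists that held with an estimated correlation rest on that test.

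Kdm5d, a gene of the Y chromosome, was 4.88 to 10.7 in all libraries. Other Y chromosome genes were lower, with Ddx3y at 0 to 1.04, Uty at 0 to 3.37 and Eif2s3y at 0 to 1.01. The sex of the mice was not read from these values.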
